A study of Mus musculus with 35 samples.

How the data were processed

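Hippocampal total RNA of 35 mice was measured by the submitters on the NanoString nCounter platform, which counts fluorescent barcodes bound to each target RNA, with a mouse panel of Alzheimer disease genes. The deposited table holds 1 column per mouse and 760 genes. Its values were normalized and put on the log2 scale by the authors, as deposited. They were used as they stand, with no pseudocount, no filter on level and no further scaling. The series text names the Rosalind platform as the submitters' analysis environment. The normalization reference, the treatment of background and the raw counts are not given in the sources used here. No panel reference gene was recognised among the 760 symbols, so a rescaling on such genes was not run. Of the symbols, 750 were found in the mouse gene table of assembly GRCm38.p6, and 10 were not found. Among the 595 pairs of mice, at most 4.21% of genes had equal values (within 0.005), so no column was a copy of another.

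Each gene was fitted with limma (lmFit, contrasts.fit, eBayes) with the 5 groups and sex as terms. All 35 mice were in the fit, so the groups shared 1 estimate of the spread. Tests were two-sided. P-values were adjusted by the Benjamini-Hochberg method over the 760 genes of each comparison, with a threshold of 0.05. Differences are log2 values with the standard error (SE) of that fit, and a fold is 2 to that power. Chance alone would place 38 of 760 genes at an unadjusted p below 0.05. The sex differences of an effect came from a fit with a mean for each group and sex.

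The comparisons, the gene lists, the genes to name and most alternative settings were chosen before the data were examined. The genes named in the 5 main comparisons and for sex were those past the threshold. Where fewer than 5 passed, they were the 5 with the smallest p, given as values. To these came up to 4 members with the smallest p of each list described, and the check genes App and Mapt. Polb and Ctsz, which the same rule lists, were not analysed here, and some other genes it would name are not described here. For the other comparisons the genes with the smallest p are given by the same order, a choice made after the values were seen.

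Of the 25 lists, 16 had at least 4 measured members and were tested. These were disease-associated microglia (6 genes), general microglia and myeloid (6), complement (4), general astrocyte (5), oligodendrocyte and myelin (27), excitatory neuron and glutamate receptor (4), inhibitory neuron and GABA (5), synaptic vesicle and presynapse (24), postsynapse (5), lysosome and cathepsin (15), autophagy and mitophagy (4), oxidative phosphorylation and mitochondria (12), proteasome and protein folding (20), amyloid precursor and tau pathway (5), Alzheimer risk locus (8), and endothelium and vessel wall (5). The other 9 had fewer members and were not tested. They were homeostatic microglia, interferon response and antigen presentation, cytokines and inflammatory signalling, reactive astrocyte, oligodendrocyte precursor, immediate early and activity-dependent, DNA repair and DNA damage response, choroid plexus and blood, and panel reference gene. Among the tested lists, oxidative phosphorylation and mitochondria is called oxidative phosphorylation below. It also holds Mfn1, which entered for the mitochondria part of its name, and Got1, which encodes a cytosolic aminotransferase.

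Lists were tested with limma's camera, which asks whether the members differ more than the other genes, with a preset correlation between genes of 0.01. Camera with the correlation estimated from the data, fry, and a permutation of the mice within sex on the mean of the list were run beside it. Fry asks whether the members move, on balance, 1 way, and does not compare them with other genes. The permutation was exact where 2 groups were compared, and used 100000 draws for sex and for the averaged treatment effect. The permutation was added after the data were seen. List p-values were adjusted over the 16 lists of a comparison. Over the 192 pairs of list and comparison, camera called 36, and in 0 of these did the median, the mean and the direction of the test differ in sign. They differed in sign in 29 of the pairs not called. In 14 of these the mean and the median themselves had opposite signs, and in 15 they had 1 sign and the test the other, which can arise because camera compares a list with the other genes and not with 0.

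The fit was tried on 20 made-up data sets of 760 genes in which 200 were changed, at the group sizes of WT_veh and AD_veh. With independent noise it recovered 70.2% of changes of 0.5 and 94.55% of changes of 1 on the log2 scale, and 3.39% of its calls were false. With whole-mouse residuals reshuffled, which keeps the correlation between genes, the same shares were 67.9%, 93.65% and 4.13%. The adjusted threshold is easier to pass where many genes change, as the 200 did here. These shares therefore do not tell how many such changes would be found where few genes pass. R 4.3.3, limma 3.58.1, Python 3.11.15 and matplotlib 3.10.9 were used.

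Alternatives fixed in advance were replicate number as a block, no sex term, only the groups compared, median centring, quantile normalization, leaving out the dimmest 25% of genes, trend and robust moderation, sample weights, and leaving out each mouse in turn. Added after the data were seen were the per-mouse mean of the myelin list (the myelin score) as a covariate, the first principal component or the sample median as a covariate for sex, leaving out 3 mice with Adora2a above 7 on the log2 scale, leaving out each mouse in turn in the list tests, and a comparison of all 4 transgenic groups with WT_veh. For each comparison 100 splits of the same mice, the real one included, were fitted in the same way. Similarities between effects that share mice were set against 100 simulated sets of unchanged groups.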

Results

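The data describe the hippocampus of 35 mice aged 18 months, in 5 groups. The 3xTgAD mouse carries human APP and MAPT (tau) transgenes and develops amyloid and tau pathology. In the 3xTgAD/Polb+/- mouse, 1 copy of Polb, the gene of DNA polymerase beta of base excision repair, is lost as well. Mice received vehicle or Urolithin A, a gut microbial metabolite of ellagitannins known to stimulate mitophagy, by oral gavage at 200 mg/kg/day for 5 months. The groups were wild-type with vehicle (WT_veh, 7 mice), 3xTgAD with vehicle (AD_veh, 8), 3xTgAD/Polb+/- with vehicle (ADPolB_veh, 7), 3xTgAD with Urolithin A (AD_UA, 7) and 3xTgAD/Polb+/- with Urolithin A (ADPolB_UA, 6). There were 17 males and 18 females, and no treated wild-type mice, so the effect of Urolithin A could be measured only in transgenic mice.

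The value for each gene and mouse is a normalized barcode count on the log2 scale. The median over 760 genes ranged from 8.60 in AD_UA 3 to 9.12 in AD_veh 2, with group means of 8.79 ± 0.14 (SD, n = 7) in WT_veh, 8.85 ± 0.13 (n = 8) in AD_veh, 8.92 ± 0.12 (n = 7) in ADPolB_veh, 8.79 ± 0.12 (n = 7) in AD_UA and 8.90 ± 0.09 (n = 6) in ADPolB_UA. The depth in counts behind a value is not given in the sources used here, so the number of mice is the limit on precision used. The first principal component held 48.7% of the variance. It followed the mean of the oligodendrocyte and myelin list across the 35 mice (Pearson r = 0.954, Spearman rho = 0.948, each with permutation p = 1e-05, the smallest that 100000 draws can give). This was the 1 relation tested. The 27 genes of the list are among the 760 behind the component, so the p does not measure a relation between independent values. Without the 2 mice farthest from the median score r was 0.946, and with group and sex removed it was 0.960. The main axis of difference between mice, within groups as well, thus ran with the level of myelin genes, though not shown to do so with these alone. Lowest on the component were WT_veh 6, AD_UA 3 and WT_veh 1, with sample medians of 8.665, 8.595 and 8.64. Highest were AD_veh 2, ADPolB_UA 5 and ADPolB_veh 6, with 9.115, 9.07 and 9.085. A level shared by all genes was thus not told apart from the myelin genes on this axis. Relations of the component with the sample median or with other lists were not tested.

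The comparison of AD_veh with WT_veh addresses the effect of the 3xTgAD genotype. Acp1, which encodes the low molecular weight protein tyrosine phosphatase, fell to 0.707-fold (log2 -0.50, SE 0.10, adjusted p = 0.0295, 8 and 7 mice), from 6.38 ± 0.21 (SD, n = 7) to 5.88 ± 0.11 (n = 8). It was the only gene past the threshold, and 50 of 760 genes had an unadjusted p below 0.05 (33 higher, 17 lower; 31 and 32 with median centring, 29 and 34 with quantile normalization). That count was 114, 95, 99 and 77 without WT_veh 5, WT_veh 8, AD_veh 3 and AD_veh 5, and 33 without WT_veh 6 or AD_veh 6. Next by p were Tbc1d9, a member of the TBC domain family (0.594-fold, log2 -0.75, SE 0.19, adjusted p = 0.139), Mapt, the tau gene (1.38-fold, 0.46, SE 0.12, adjusted p = 0.175), Ppp1cc, a catalytic subunit of protein phosphatase 1 (1.24-fold, adjusted p = 0.175), and Bex1 (0.711-fold, adjusted p = 0.293). App was at 0.991-fold (adjusted p = 0.943). The direction of App turned when WT_veh 8 or AD_veh 8 was left out (0.00 and 0.01).

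All 27 oligodendrocyte and myelin genes had a higher mean in AD_veh than in WT_veh, with a median log2 difference of 0.55 (camera adjusted p = 3.90e-07, adjusted p = 0.857 with an estimated correlation). The list mean was 9.59 ± 0.69 (SD, n = 8) against 9.05 ± 0.79 (n = 7), and 7 of 8 AD_veh mice lay above the WT_veh mean. Examples are Mbp, myelin basic protein (1.70-fold, log2 0.76, SE 0.36), Mog (1.65-fold), Nkx6-2 (1.58-fold) and Ndrg1 (1.40-fold). The median was 0.345 without WT_veh 6 and 0.336 without AD_veh 2. Of the 24 presynaptic genes 20 were lower (median -0.09, camera adjusted p = 0.00118, adjusted p = 0.857 with an estimated correlation), among them Stx1a, a SNARE protein of vesicle fusion (0.647-fold), Rab3c (0.757-fold) and Syngr1 (0.850-fold). Their list mean was 11.28 ± 0.32 (SD, n = 8) against 11.41 ± 0.18 (n = 7), and 4 of 8 AD_veh mice lay below the WT_veh mean. Without AD_veh 2 the median was -0.0136 and the call was lost (camera adjusted p = 0.942), and the median was -0.0583, -0.141, -0.154 and -0.133 without WT_veh 1, WT_veh 5, AD_veh 1 and AD_veh 4. Of the 20 proteasome and protein folding genes 14 were lower (median -0.07, camera adjusted p = 0.0141, adjusted p = 0.857 with an estimated correlation), among them Psmc1 (0.887-fold), Stip1 (0.898-fold), Hspa4 (0.871-fold) and Hspb8 (0.741-fold). Their list mean lay below that of WT_veh in 7 of 8 AD_veh mice, and the call was lost without AD_veh 2 (median -0.0179, camera adjusted p = 0.506) or WT_veh 6 (-0.0306, 0.158). Without AD_veh 2, AD_UA 3 and AD_UA 8, a set chosen after the values were seen, camera called 1 list here, myelin. The other 13 lists had medians from -0.06 (inhibitory neuron and GABA) to 0.36 (general microglia and myeloid) and camera adjusted p of 0.208 or more. Over all genes 0 list members were called by limma, and adjusted over the list alone 1 was, Mapt in the amyloid precursor and tau list. By fry 0 of 16 lists passed (smallest adjusted p = 0.624), and by exact permutation 0 (smallest adjusted p = 0.818, 0 lists at an unadjusted p below 0.05). The Acp1 call was lost with quantile normalization (adjusted p = 0.0771) and with trend and robust moderation (0.0598), and it was lost without any 1 of WT_veh 1, 2, 5, 7 or 8 or AD_veh 5, 6 or 8. Among the 570 genes left without the dimmest 25% Acp1 was absent, and limma called 0.

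**Figure D1:**
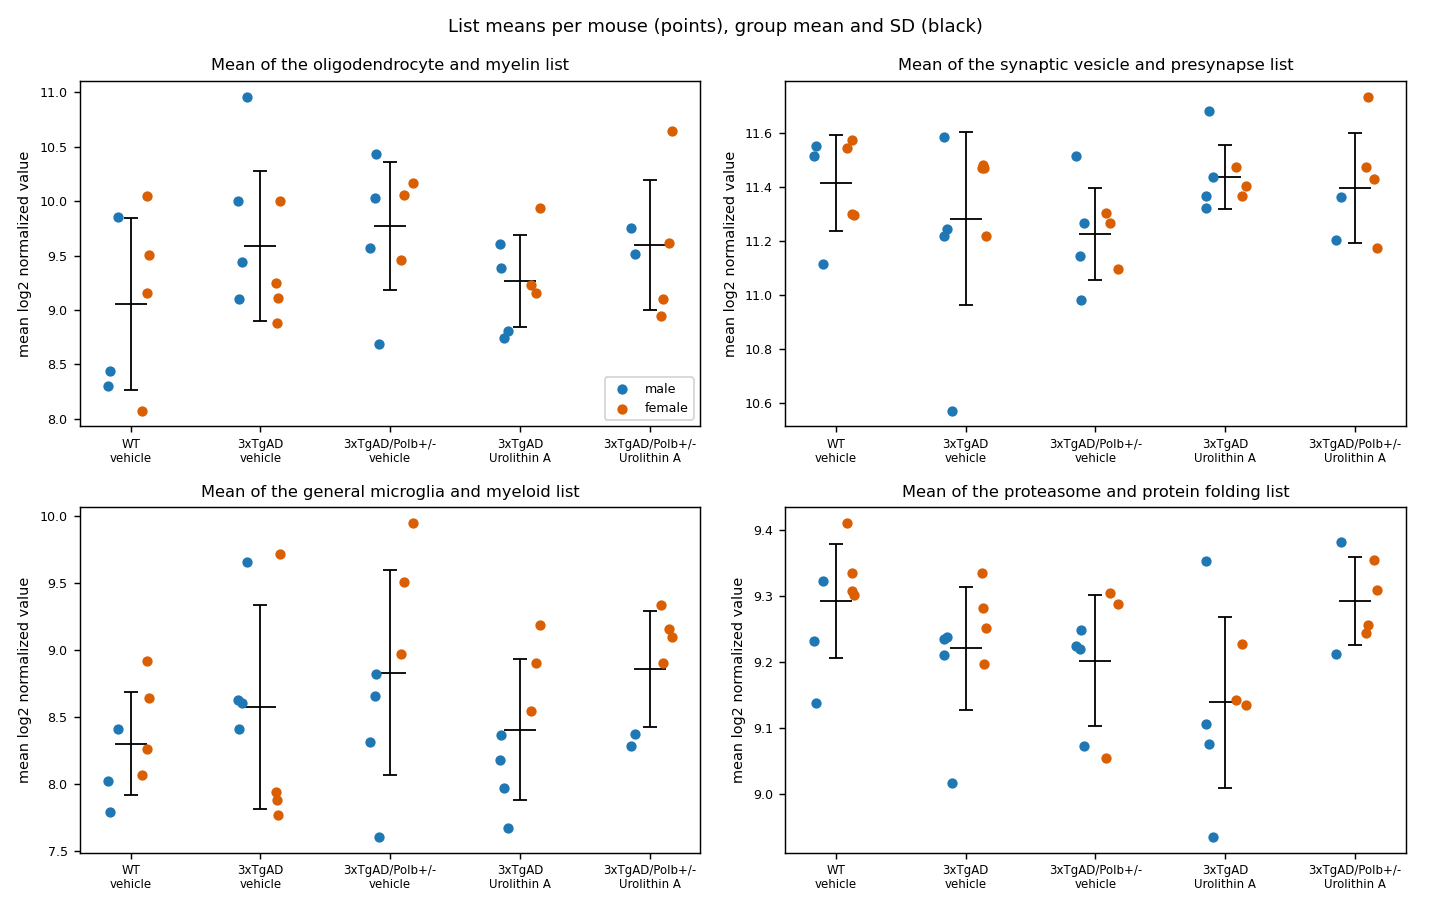
Mean log2 normalized value of 4 gene lists (vertical axes) in each mouse (points, males blue, females orange) of the 5 groups (horizontal axes), with the group mean and SD in black. The myelin list means of WT_veh and AD_veh were 9.05 and 9.59, and single mice within a group lay as far apart as 8.07 and 10.05 in WT_veh.

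The comparison of ADPolB_veh with WT_veh addresses the combined genotype. Limma called 0 of 760 genes, while 196 had an unadjusted p below 0.05 (157 higher, 39 lower). The balance of directions depended on the scaling, with 88 higher and 133 lower under median centring and 82 and 101 under quantile normalization. The count was 108 without WT_veh 1 or WT_veh 2, 84 without WT_veh 6, 81 without ADPolB_veh 6 and 280 without WT_veh 5. The smallest p belonged to Acp1 (0.712-fold, log2 -0.49, SE 0.11, adjusted p = 0.0597, 7 and 7 mice). It was followed by Bex1 (0.659-fold, log2 -0.60, SE 0.15), Fam171a1 (0.785-fold, -0.35, SE 0.09) and Slc41a1, a magnesium transporter (1.40-fold, 0.48, SE 0.13), each with an adjusted p of 0.133, and by Tmcc1 (1.22-fold, adjusted p = 0.178). Mapt was at 1.27-fold (log2 0.34, SE 0.13, adjusted p = 0.178) and App at 0.984-fold. App turned direction with sample weights (0.03) and without ADPolB_veh 1 or 5 (0.02 and 0.01).

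Glial genes of several kinds had higher means in ADPolB_veh than in WT_veh. All 27 myelin genes were higher (median 0.69, camera adjusted p = 3.02e-05, adjusted p = 0.450 with an estimated correlation), in 6 of 7 mice against the WT_veh mean, with Nkx6-2 at 1.93-fold (log2 0.95, SE 0.35), Tmem63a at 1.91-fold, Mbp at 1.95-fold and Sirt2 at 1.33-fold. Lists with higher medians that camera did not call were complement (0.80, 4 of 4 genes), general microglia and myeloid (0.69, 5 of 6), disease-associated microglia (0.49, 5 of 6) and endothelium and vessel wall (0.36, 5 of 5), each with a camera adjusted p of 0.0667, and general astrocyte (0.27, 5 of 5, 0.0934), lysosome and cathepsin (0.25, 0.258) and Alzheimer risk locus (0.20, 0.247). Lower as lists were synaptic vesicle and presynapse (22 of 24 genes, median -0.12, camera adjusted p = 5.61e-05), proteasome and protein folding (16 of 20, -0.12, 0.000519) and oxidative phosphorylation (10 of 12, -0.13, 0.0108), each with adjusted p = 0.450 with an estimated correlation. These 3 calls held without any 1 mouse, with a median of -0.183 for presynapse without WT_veh 5, -0.0675 for proteasome without ADPolB_veh 5 and -0.0579 for oxidative phosphorylation without ADPolB_veh 1. Among their members were Rab3c (0.628-fold, log2 -0.67, SE 0.22), Stx1a (0.609-fold), Napb (0.796-fold), Psmc1 (0.853-fold), Dnajb4 (0.854-fold), the ATP synthase genes Atp5a1 (0.898-fold) and Atp5h (0.907-fold), and Got1 (0.877-fold). Atp5a1 and Got1 were the 2 members of the oxidative phosphorylation list with an unadjusted p below 0.05. Medians of the lists without a call were -0.14 for excitatory neuron and glutamate receptor, -0.10 for inhibitory neuron and GABA, 0.05 for postsynapse, -0.04 for autophagy and mitophagy and 0.00 for the amyloid precursor and tau pathway. Adjusted over the list alone, limma called 17 genes in 6 lists, 5 of 6 in general microglia and myeloid, 4 of 6 in disease-associated microglia, 4 of 4 in complement, 2 in general astrocyte and 1 each in Alzheimer risk locus and endothelium, against 0 over all genes. By fry 0 of 16 lists passed (smallest adjusted p = 0.124), and by exact permutation 0 (smallest adjusted p = 0.170, 3 lists at an unadjusted p below 0.05). With the myelin score as a covariate, a setting added after the data were seen, 49 genes instead of 196 had an unadjusted p below 0.05 and the 1 called gene was Acp1 (adjusted p = 0.0489). Estimated sample weights gave 441 calls (323 higher, 118 lower), and leaving out WT_veh 5 gave 5.

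The direct comparison of ADPolB_veh with AD_veh addresses the lost Polb copy within 3xTgAD. Limma called 0 genes, and 33 had an unadjusted p below 0.05 (24 higher, 9 lower). The balance turned to 17 and 22 with median centring and 15 and 35 with quantile normalization, and the count was 114 without AD_veh 2, 65 without ADPolB_veh 2, 18 without ADPolB_veh 7 and 15 without ADPolB_veh 6. The smallest p were those of Fam171a1 (0.780-fold, log2 -0.36, SE 0.09, adjusted p = 0.236, 7 and 8 mice), Cd2ap, an adaptor protein at an Alzheimer risk locus (1.29-fold), Trappc4 (0.866-fold), Cox6c, a subunit of cytochrome c oxidase (0.699-fold), and Wls, which carries Wnt proteins through secretion (1.32-fold), the last 4 with an adjusted p of 0.873. Complement genes were higher in 4 of 4 (median 0.49, camera adjusted p = 0.0332), with C1qa at 1.43-fold (log2 0.51, SE 0.36), C1qb at 1.35-fold, C1qc at 1.38-fold and Serping1 at 1.63-fold. Endothelial genes were higher in 5 of 5 (0.31, 0.0323), with Pecam1 at 1.25-fold and Cldn5 at 1.24-fold. Lower as lists were oxidative phosphorylation (10 of 12 genes, -0.06, camera adjusted p = 0.0178), synaptic vesicle and presynapse (16 of 24, -0.04, 0.0323) and proteasome and protein folding (14 of 20, -0.04, 0.0323). Of the 7 ADPolB_veh mice 5 lay below the AD_veh mean for presynapse and 3 for proteasome. All 5 list calls depended on single mice. Without AD_veh 2 the median was -0.152 for presynapse and -0.0763 for proteasome and camera called 8 lists, as it did without AD_veh 2, AD_UA 3 and AD_UA 8 together. The presynapse call was lost without any 1 of AD_veh 1, 3, 4, 5 or 8 or ADPolB_veh 3, 4, 6 or 7 (camera adjusted p of at most 0.440), and its median turned above 0 without AD_veh 1 (0.0362), AD_veh 3, ADPolB_veh 6 or ADPolB_veh 7 and was -0.0833 without ADPolB_veh 2. The proteasome call was lost without any 1 of AD_veh 3, 4, 5 or 8 or ADPolB_veh 5 or 6 (at most 0.186), with a median of -0.0202 and -0.0633 without ADPolB_veh 1 and 2. The oxidative phosphorylation call was lost without AD_veh 8 (0.113), with a median of -0.0363, -0.0319 and -0.0963 without ADPolB_veh 1, 5 and 7. The complement call was lost without any 1 of AD_veh 3, 4 or 5 or ADPolB_veh 2, 3, 4, 5 or 6 (at most 0.146) and the endothelial call without any 1 of AD_veh 6, 7 or 8 or ADPolB_veh 1, 4 or 5 (at most 0.231). With an estimated correlation the adjusted p was 0.445 for 4 of these lists and 0.655 for presynapse. By fry and by exact permutation 0 lists passed (smallest adjusted p = 0.564 and 0.712, 0 lists at an unadjusted permutation p below 0.05), and limma called 0 members both over all genes and adjusted over the list alone. App and Mapt were at 0.994-fold and 0.919-fold, and the direction of App turned with sample weights (0.03). With sample weights limma called 209 genes in place of 0.

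Across the 760 genes the differences of AD_veh and of ADPolB_veh from WT_veh correlated (r = 0.76, across genes, which are not independent replicates). Both differences share the WT_veh mice. Groups simulated without any effect, with the same shared mice, gave a mean r of 0.50 with 95% of draws between -0.31 and 0.90, and 25 of 100 draws reached the measured r. With the 7 WT_veh mice parted into 3 and 4 so that no mouse was shared, r averaged 0.48 over 35 splits (-0.14 to 0.67). At an unadjusted p below 0.05, 22 genes were higher in both (6.82 by chance if independent) and 10 lower in both (0.872), a comparison that the shared mice also favour.

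The comparison of AD_UA with AD_veh addresses the effect of Urolithin A in 3xTgAD mice. Limma called 0 genes, and 71 had an unadjusted p below 0.05 (30 higher, 41 lower; 33 and 33 with median centring, 36 and 39 with quantile normalization). The count was 108 without AD_UA 1, 32 without AD_UA 3, 37 without AD_UA 8 and 41 without AD_UA 7. The smallest p were those of Fam171a1 (0.792-fold, log2 -0.34, SE 0.09) and Gja1, the astrocyte gap junction protein connexin 43 (0.787-fold, -0.35, SE 0.10), each with an adjusted p of 0.393 (7 and 8 mice), and of Wscd2 (0.743-fold), Tor1a (0.840-fold) and C130074G19Rik (2.23-fold, log2 1.16, SE 0.37), each with 0.472. Of the 24 presynaptic genes 22 were higher in treated mice (median 0.14, camera adjusted p = 7.57e-06, adjusted p = 0.997 with an estimated correlation), with Stx1a at 1.79-fold (log2 0.84, SE 0.32), Syngr1 at 1.20-fold and Snap91 at 1.18-fold. The list mean was 11.44 ± 0.12 (SD, n = 7) against 11.28 ± 0.32 (n = 8), and all 7 treated mice lay above the vehicle mean. Of the 27 myelin genes 26 were lower (median -0.31, camera adjusted p = 0.0227, adjusted p = 0.997 with an estimated correlation), with Sox8 at 0.784-fold, Tppp3 at 0.654-fold, Anln at 0.638-fold and Ndrg1 at 0.767-fold. Both calls were lost without AD_veh 2 (presynapse median 0.0705, camera adjusted p = 0.539, myelin -0.102, 0.648), and that of myelin also without any 1 of AD_veh 6 or 7 or AD_UA 1, 5 or 8 (at most 0.172). The presynapse median was 0.0838 without AD_UA 8. The other 14 lists had medians from -0.16 (disease-associated microglia) to 0.22 (inhibitory neuron and GABA), and 1 member was called adjusted over the list alone, against 0 over all genes. By fry and by exact permutation 0 lists passed (smallest adjusted p = 0.615 and 0.669, 0 lists at an unadjusted permutation p below 0.05). App differed by 0.00 on the log2 scale, Mapt was at 0.906-fold, and the sign of App depended on the setting and on single mice.

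The mice AD_veh 2, AD_UA 3 and AD_UA 8 stood apart in this comparison by a high level of Adora2a, an adenosine receptor gene that is abundant in the striatum, a gene and a grouping of mice chosen after the values were seen (9.85, 8.60 and 7.13, against 6.07 in ADPolB_UA 6 and at most 4.79 in the other mice). AD_veh 2 had the lowest presynapse mean of its group (10.57) and AD_UA 8 the highest of its own (11.68). Without these 3 mice camera called 0 lists, the myelin and presynapse lists pointed the other way (adjusted p = 0.714 and 0.828), and 18 genes in place of 71 had an unadjusted p below 0.05.

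The comparison of ADPolB_UA with ADPolB_veh addresses the same treatment in 3xTgAD/Polb+/- mice. Limma called 0 genes, and 43 had an unadjusted p below 0.05 (21 higher, 22 lower), or 28 without ADPolB_UA 2. The smallest p were those of Add2, the membrane skeleton protein beta-adducin (0.758-fold, log2 -0.40, SE 0.10, adjusted p = 0.238, 6 and 7 mice), Bcl2, which inhibits apoptosis (1.49-fold, 0.57, SE 0.16), Reep1 (1.22-fold), Slc8a2, a sodium/calcium exchanger (0.717-fold), and Lgr5, a receptor of R-spondins (1.79-fold), the last 4 with an adjusted p of 0.381. Higher as lists were synaptic vesicle and presynapse (23 of 24 genes, median 0.16, camera adjusted p = 0.00262, adjusted p = 0.673 with an estimated correlation), proteasome and protein folding (17 of 20, 0.07, 0.0124) and oxidative phosphorylation (11 of 12, 0.09, 0.0402), the last 2 with adjusted p = 0.546 with an estimated correlation. Examples are Rab3c (1.52-fold, log2 0.61, SE 0.23), Sv2a (1.13-fold), Stip1 (1.16-fold), Hsp90aa1 (1.12-fold) and Atp5a1 (1.09-fold). Endothelial genes were lower in 5 of 5 (median -0.26, camera adjusted p = 0.0334, adjusted p = 0.546 with an estimated correlation), with Pecam1 at 0.841-fold and Esam at 0.834-fold. The presynapse call was lost without ADPolB_UA 6 (median 0.0898, camera adjusted p = 0.0764) and the proteasome call without ADPolB_veh 5 or ADPolB_UA 1 (0.0908 and 0.101). ADPolB_UA 6 had the highest presynapse mean of its group (11.73) and the next highest Adora2a (6.07) after the 3 mice above. The oxidative phosphorylation call was lost without any 1 of ADPolB_veh 1, 4, 5 or 6 or ADPolB_UA 1, 4, 5 or 6 (at most 0.1497) and the endothelial call without any 1 of ADPolB_veh 1, 4 or 5 or ADPolB_UA 1, 3 or 6 (at most 0.190). The other 12 lists had medians from -0.38 (complement) to 0.04 (amyloid precursor and tau pathway), and 1 member was called adjusted over the list alone, against 0 over all genes. By fry and by exact permutation 0 lists passed (smallest adjusted p = 0.453 and 0.564, 0 lists at an unadjusted permutation p below 0.05). App was at 1.04-fold and Mapt at 1.07-fold, and without ADPolB_veh 1 the sign of Mapt turned (-0.01). Leaving out ADPolB_UA 6 gave 1 call, Add2, and sample weights gave 20.

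**Figure D2:**
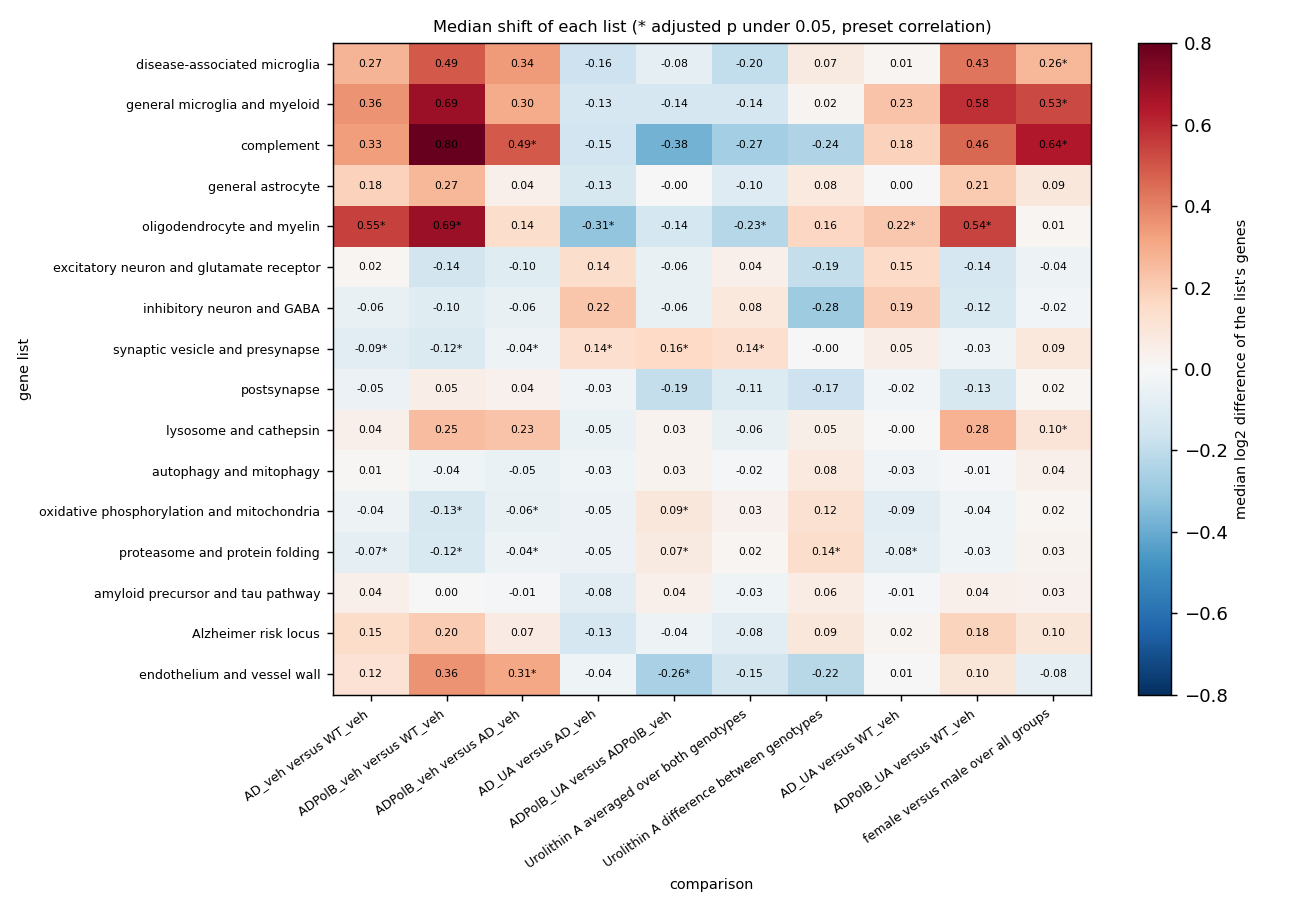
Median log2 difference of the members of each tested list (vertical axis) in 10 comparisons (horizontal axis), coloured from lower (blue) to higher (red), with a star at a camera adjusted p below 0.05 with the preset correlation. The myelin list had medians of 0.55 and 0.69 in the vehicle groups against WT_veh and -0.31 in AD_UA against AD_veh, and 0 of the starred values passed with an estimated correlation.

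Averaged over both genotypes, Urolithin A gave 0 limma calls and 90 genes at an unadjusted p below 0.05 (39 higher, 51 lower), or 58 without ADPolB_veh 6. The smallest p were those of Add2 (0.819-fold, log2 -0.29, SE 0.07, adjusted p = 0.110, 13 treated and 15 vehicle mice), Lnx1 (1.37-fold, adjusted p = 0.194) and Prex2 (0.830-fold, adjusted p = 0.235). All 24 presynaptic genes were higher in treated mice (median 0.14, camera adjusted p = 4.74e-07) and all 27 myelin genes lower (-0.23, 0.0106), each with adjusted p = 0.824 with an estimated correlation. By fry and by permutation 0 lists passed (smallest adjusted p = 0.644 and 0.641). Without the 3 mice with high Adora2a, camera called 1 of these lists, close to the threshold (adjusted p = 0.0496). The myelin call was lost without any 1 of AD_veh 2, ADPolB_veh 7, AD_UA 8 or ADPolB_UA 3 or 6 (camera adjusted p of at most 0.213), and its median was -0.139 without AD_veh 2 and -0.346 without ADPolB_veh 1. The test of the difference between the effects in both genotypes gave 0 limma calls and 29 genes at an unadjusted p below 0.05 (54, 46, 19 and 45 without AD_veh 2, AD_UA 1, AD_UA 3 and AD_UA 5), with Glud1 first (1.27-fold, adjusted p = 0.875). All 20 proteasome and protein folding genes had a more positive effect of Urolithin A in 3xTgAD/Polb+/- mice (median 0.14, camera adjusted p = 0.0257, adjusted p = 0.646 with an estimated correlation, fry adjusted p = 0.377). With median centring camera called 0 lists here, and the call was lost without any 1 of 12 of the 28 mice (AD_veh 3, 4, 5 or 8, ADPolB_veh 5, 6 or 7, AD_UA 2 or 6 or ADPolB_UA 1, 4 or 6, camera adjusted p of at most 0.215), with a median of 0.0741 without AD_UA 3.

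The effect of Urolithin A and that of the genotype share the vehicle mice, which by itself makes them point in opposite directions. Across genes the AD_UA effect correlated with the AD_veh effect at r = -0.64, against a mean of -0.43 (-0.86 to 0.30) in groups simulated without effects, of which 33 of 100 reached the measured r. With the AD_veh mice parted 4 and 4, r averaged -0.22 over 35 splits (-0.45 to 0.22). In 3xTgAD/Polb+/- mice r was -0.62, the simulated mean -0.50 (-0.89 to 0.20), 37 of 100 draws were as extreme, and the parted mean was -0.34 (-0.48 to 0.04). Of the 50 genes with an unadjusted p below 0.05 in AD_veh, 45 (90.0%) had a treatment effect of the opposite sign, and of the 196 in ADPolB_veh 179 (91.3%), against 73.0% and 74.3% of all genes. Acp1, the 1 gene called in AD_veh, was not among those 45. The 2 treatment effects correlated at r = 0.40 across genes (simulated mean -0.00, -0.55 to 0.72, 17 of 100 draws as extreme). At an unadjusted p below 0.05 they shared 1 higher gene and 2 lower genes (1.19 by chance if independent).

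Against WT_veh, Acp1 was also the 1 gene called in AD_UA (0.642-fold, log2 -0.64, SE 0.11, adjusted p = 0.00113, 7 and 7 mice) and in ADPolB_UA (0.690-fold, -0.54, SE 0.11, adjusted p = 0.0302, 6 and 7 mice). These calls and that in AD_veh rest on the same 7 WT_veh mice, so they are not independent of each other. At an unadjusted p below 0.05 there were 41 genes (15 higher, 26 lower) and 76 genes (58 higher, 18 lower). The second balance turned to 30 and 42 with median centring and 24 and 52 with quantile normalization. The first count was 62 and 64 without AD_UA 1 and AD_UA 5, and the second 142, 46, 50, 31 and 124 without WT_veh 5, WT_veh 6, ADPolB_UA 2, ADPolB_UA 5 and ADPolB_UA 6. Mapt was at 1.25-fold (adjusted p = 0.641) and 1.36-fold (0.284). In AD_UA the myelin list had a median of 0.22 (camera adjusted p = 0.0366, adjusted p = 0.938 with an estimated correlation), and 17 of 20 proteasome and protein folding genes were lower (-0.08, 0.00148, adjusted p = 0.713 with an estimated correlation). In ADPolB_UA all 27 myelin genes were higher (0.54, camera adjusted p = 0.000757, adjusted p = 0.532 with an estimated correlation). The myelin call in AD_UA was lost without any 1 of WT_veh 1, 2 or 6 or AD_UA 1, 2, 5 or 6 (camera adjusted p of at most 0.715, median 0.0596, 0.373 and 0.377 without WT_veh 6, 5 and 8). The proteasome call was lost without WT_veh 6 (0.0634), and the myelin call in ADPolB_UA without WT_veh 6 or ADPolB_UA 5 (0.0662 and 0.0645, medians 0.346 and 0.315). Adjusted over the list alone 0 members were called in AD_UA and 1 in ADPolB_UA, against 0 over all genes. By fry and by exact permutation 0 lists passed in AD_UA (smallest adjusted p = 0.434 and 0.536, 1 list at an unadjusted permutation p below 0.05) and 0 in ADPolB_UA (0.389 and 0.103, 4 lists). Both Acp1 calls were lost in fits of only the groups compared (adjusted p = 0.109 and 0.168), and that in ADPolB_UA also with trend and robust moderation (0.0612) and without any 1 of WT_veh 1, 2, 7 or 8 or ADPolB_UA 1, 2, 4 or 6. Leaving out AD_UA 1 or AD_UA 2 gave 3 and 2 calls in AD_UA.

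**Figure D3:**
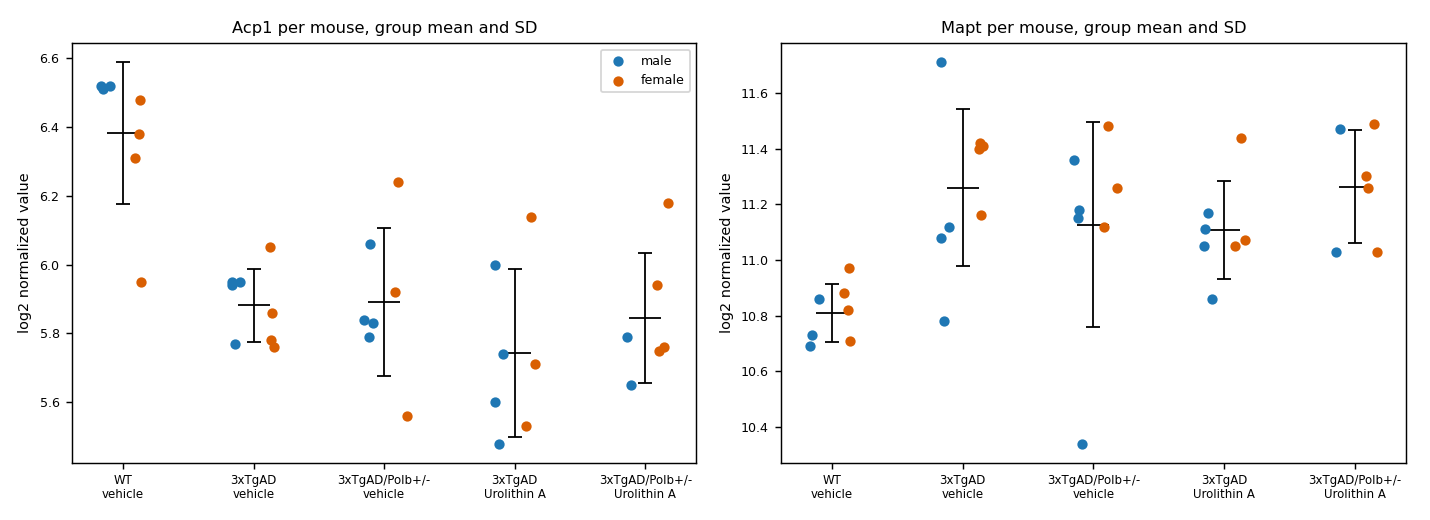
Log2 normalized value (vertical axes) of Acp1 and Mapt in each mouse (points, males blue, females orange) of the 5 groups (horizontal axes), with the group mean and SD in black. All 28 transgenic mice (highest 6.24) lay below 6 of the 7 WT_veh mice for Acp1 (5.95 in WT_veh 3, 6.31 or more in the others), and 26 of 28 lay above the WT_veh mean for Mapt.

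The comparison of 18 females with 17 males, with group in the fit, gave 0 limma calls and 65 genes at an unadjusted p below 0.05 (60 higher in females, 5 lower). The lean to females was smaller with median centring (40 higher, 24 lower) and quantile normalization (39 and 33). The smallest p were those of Cd74, the invariant chain of MHC class II (2.82-fold, SE 0.34 on the log2 scale, adjusted p = 0.0812), B2m, the light chain of MHC class I (1.59-fold, 0.67, SE 0.19), Med29 (1.10-fold), Anxa2 (1.48-fold) and Fxyd5 (1.32-fold), the last 4 with an adjusted p of 0.248. Complement genes were higher in females in 4 of 4 (median 0.64, camera adjusted p = 6.42e-05, adjusted p = 0.307 with an estimated correlation), with C1qa at 1.68-fold (log2 0.75, SE 0.24), C1qb at 1.60-fold, C1qc at 1.52-fold and Serping1 at 1.49-fold. General microglia and myeloid genes were higher in 6 of 6 (0.53, 6.42e-05, adjusted p = 0.434 with an estimated correlation), with Fcer1g at 1.54-fold, Lcp1 at 1.45-fold, Ctss at 1.45-fold and Cyba at 1.43-fold. Disease-associated microglia genes were higher in 6 of 6 (0.26, 0.0210, adjusted p = 0.684 with an estimated correlation), with Tyrobp at 1.61-fold, Apoe at 1.24-fold and Axl at 1.19-fold, a call lost without AD_veh 6, ADPolB_veh 1 or ADPolB_veh 6 (0.0709, 0.0590 and 0.0619). Lysosome and cathepsin genes were higher in 14 of 15 (0.10, 0.00425, adjusted p = 0.563 with an estimated correlation), with Grn, progranulin, at 1.31-fold. The myelin list did not lean to a sex (median 0.01).

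The means by group and sex are given as values. For single genes a difference between the groups is not shown by the test of the sex difference of the AD_veh effect (0 limma calls, smallest adjusted p = 0.913). For lists camera called 4 in that test, among them complement (adjusted p = 0.0317) and general microglia and myeloid (0.000980). With an estimated correlation 0 were called (0.836 for these 2). C1qa was higher in females by 0.86 in WT_veh, 1.43 in ADPolB_veh, 1.23 in AD_UA and 0.86 in ADPolB_UA on the log2 scale, and -0.43 in AD_veh. B2m (-0.31) and Tyrobp (-0.60) were also lower in the females of AD_veh, and Cd74 was higher in females in all 5 groups. Adjusted over the list alone limma called 10 genes, 4 of 4 in complement, 4 of 6 in general microglia and myeloid, 1 in disease-associated microglia, and Grn in both lysosome and cathepsin and Alzheimer risk locus, against 0 over all genes. By fry and by permutation 0 lists passed (smallest adjusted p = 0.0778 and 0.0880, 2 lists at an unadjusted permutation p below 0.05). Without AD_veh 2 limma called 11 genes, and with median centring or quantile normalization 1, Cd74. App was at 1.02-fold and Mapt at 1.11-fold, and the sign of App turned with both scalings (-0.01 and -0.03).

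**Figure D4:**
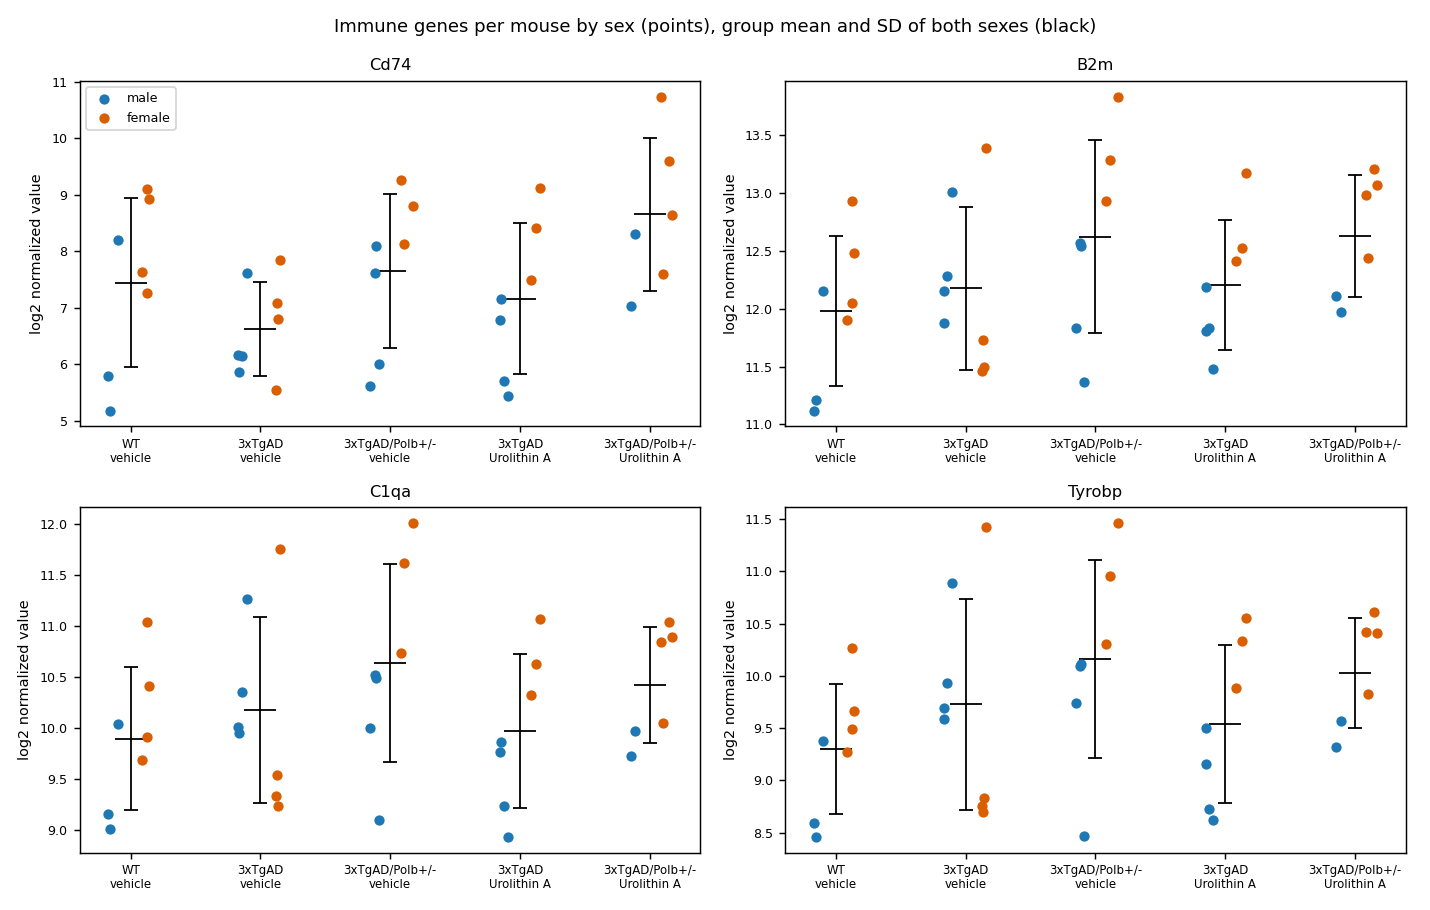
Log2 normalized value (vertical axes) of Cd74, B2m, C1qa and Tyrobp in each mouse (points, males blue, females orange) of the 5 groups (horizontal axes), with the group mean and SD of both sexes in black. For C1qa the mean of females exceeded that of males by 0.86 in WT_veh and 1.43 in ADPolB_veh, and lay below it in AD_veh (-0.43).

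The sex difference of the AD_veh effect gave 0 limma calls and 13 genes at an unadjusted p below 0.05 (66, 34, 64 and 49 without WT_veh 5, WT_veh 6, AD_veh 1 and AD_veh 6, 8 without WT_veh 1 or AD_veh 4 and 7 without WT_veh 2), with Ift27 first (log2 -0.60, SE 0.19, adjusted p = 0.913). The sex difference of the Urolithin A effect gave 0 limma calls and 4 such genes (19, 12 and 9 without AD_veh 6, AD_veh 1 and ADPolB_UA 6, 8 without ADPolB_veh 2 or AD_UA 1, and 7 without AD_veh 7, ADPolB_veh 7, ADPolB_UA 1 or ADPolB_UA 5), with Tmem165 first (0.31, SE 0.11, adjusted p = 0.998). Camera called 4 lists in each, 0 of them with an estimated correlation (smallest adjusted p = 0.836 and 0.660) and 0 by fry (0.840 and 0.908).

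Lists with fewer than 4 measured members were not tested as lists. Measured members of these lists were Tgfbr1 (homeostatic microglia), B2m and Cd74 (interferon response and antigen presentation), Tnfrsf1a and Csf1 (cytokines and inflammatory signalling), Srgn and Stat3 (reactive astrocyte), Nptx2, Vgf and Per1 (immediate early and activity-dependent) and Enpp2 (choroid plexus and blood). The DNA repair and DNA damage response list is not described further here. The oligodendrocyte precursor and panel reference gene lists had 0 measured members.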

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

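Of the tests of the 3 patterns weighed below, the split count of ADPolB_veh against WT_veh was planned before the data were seen. So were its gene counts without a mouse and with the other scalings. The reassignments of sex with the myelin covariate, the choice-of-covariate test and the splits of all transgenic mice had their bounds set before their own results were seen. They rest on a covariate and a comparison chosen after the data were seen. The other tests, with the list tests that leave out mice, were chosen only after the results were seen.

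Of 135 groups of mice and measures, 13 (9.63%) held a mouse far from the others of its group by Dixon's test, and chance alone does this in about 1 of 20. AD_veh 2 was lowest of its group in the presynapse (10.57), postsynapse (10.49) and proteasome (9.02) list means and highest in Adora2a (9.85). AD_UA 8 was highest in the presynapse (11.68) and autophagy (10.36) list means. ADPolB_veh 1 was lowest in the oxidative phosphorylation list mean (9.22) and in Mapt (10.34), ADPolB_veh 2 lowest in Adora2a (0.98), AD_UA 7 lowest in the endothelium list mean (7.09) and WT_veh 3 lowest in Acp1 (5.95). ADPolB_UA 5 was highest in the sample median (9.07) and in Tmem165 (8.51). Many of these measures were taken on the same mice and are not independent. Adora2a and the genes with the smallest p entered as measures after the values were seen, which weakens the comparison with 1 of 20.

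Some lists differed between groups of mice in the test of the difference itself. The effect of Urolithin A on proteasome and protein folding genes was more positive in 3xTgAD/Polb+/- mice (median 0.14, camera adjusted p = 0.0257, adjusted p = 0.646 with an estimated correlation). The AD_veh effect was more negative in females than in males for myelin (median -0.89, 1.16e-06), general microglia and myeloid (-0.93, 0.000980) and complement (-1.18, 0.0317) and more positive for presynapse (0.29, 4.85e-05), with adjusted p = 0.886 for myelin and 0.836 for the others with an estimated correlation. The Urolithin A effect was more positive in females for general microglia and myeloid (0.51, 0.00144), complement (0.53, 0.0421) and myelin (0.30, 0.0112) and more negative for endothelium (-0.17, 0.0165), each with adjusted p = 0.660 with an estimated correlation. Single mice decided several of these calls. Without AD_veh 2 the presynapse call of the AD_veh effect (median 0.0488, camera adjusted p = 0.338) and the complement and myelin calls of the Urolithin A effect (0.251 and 0.555) were lost. The complement call of the AD_veh effect was lost without any 1 of WT_veh 2, 3, 5 or 8 or AD_veh 1, 2, 4, 5 or 8 (at most 0.134). The myelin median of that effect was -0.568, -1.43, -0.563 and -0.482 without WT_veh 1, WT_veh 5, WT_veh 8 and AD_veh 2, the presynapse median 0.171, 0.151, 0.439 and 0.455 without WT_veh 1, WT_veh 2, WT_veh 5 and AD_veh 1, and the general microglia and myeloid median -1.44 without AD_veh 6. The complement call of the Urolithin A effect was lost without any 1 of 17 of the 28 mice (AD_veh 2, 3, 4, 5 or 8, ADPolB_veh 3, 5 or 7, AD_UA 1, 3, 5, 6 or 8 or ADPolB_UA 2, 3, 4 or 5), and its median was 0.814 without AD_veh 6. The myelin call was lost without any 1 of AD_veh 2 or 3, ADPolB_veh 3, 5 or 7, AD_UA 6 or 8 or ADPolB_UA 1 or 5, and the endothelial call without any 1 of AD_veh 7 or 8, ADPolB_veh 3 or 5, AD_UA 7 or ADPolB_UA 2 (at most 0.183), with a median of -0.322, -0.261 and -0.253 without AD_veh 2, ADPolB_veh 1 and AD_UA 6. The proteasome call was lost without any 1 of 12 of 28 mice (at most 0.215). Without the 3 mice with high Adora2a the myelin direction of the last test turned (adjusted p = 0.962).

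The first pattern is the glial genes higher in ADPolB_veh than in WT_veh. Of 100 splits of the 14 mice, 2 gave as many genes at an unadjusted p below 0.05 (196 in the real split, 345 at most in another), which was the 1 share under 0.05 among 12 comparisons (0.24 after adjustment over them), so over the 12 chance is not excluded, and the list permutation passed 0 lists (smallest adjusted p = 0.170). That count fell to 81 without ADPolB_veh 6 and rose to 280 without WT_veh 5, and its excess of higher genes (157 against 39) ended with median centring (88 against 133) and quantile normalization (82 against 101). The test of sample scaling was weak. Its bound was set after the values were seen, and the 5 glial lists were picked as higher in the same data. The mean of their 48 members, 27 of them myelin genes, was higher by 0.64 (SE 0.284) as deposited. It was higher by 0.49 (SE 0.223) with median centring and 0.52 (SE 0.231) with quantile normalization. Median centring moves all genes of a mouse alike, so taking out a shift common to all genes left 0.49. Other forms of scaling stay open. With median centring 3 of 5 astrocyte genes were higher (median 0.12), against 5 of 5 as deposited. This test replaced an earlier one on total counts, which did not bear on direction. A differing oligodendrocyte share of the dissected tissue stays open. With the myelin score as a covariate 45 of the 733 genes outside the myelin list had an unadjusted p below 0.05, against 183 without it. In other splits the median was 19 (95th percentile 66.4). A change of glial state with the genotype stays open, untested.

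The second pattern is the microglial genes higher in females, for example Cd74 (2.77-fold), C1qa (1.65-fold) and Tyrobp (1.58-fold) once the myelin score was a covariate. With it limma called 30 genes (25 higher, 5 lower), 6 of 10 myeloid and complement genes among them and 2 of the lower genes (Gpr37 and Tmem63a, chosen after their values were seen) members of the covariate's own list, against 0 without it, and 1 of 100 reassignments of sex within groups, the real one, called as many (22 at most in another). The choice of covariate cannot be told apart from the pattern: the first principal component made 27 of these calls again (35 in all), while the sample median made 12 (17 in all, 7 higher and 10 lower, with 2 of the 10 myeloid and complement genes), and the bound set in advance, which the component met, was too weak because that component follows the myelin score (r = 0.954). A higher microglial share alone cannot be told apart either: 10 microglial genes differed by 0.29 to 0.72 (mean 0.54), and with their per-mouse mean in the model the spread of their sex terms (SD 0.0929) had a permutation p of 0.156, above the 0.01 set for the last of 5 versions of this test, of which 3 on the spread (p = 0.00960 for 11 genes with Trem2, 0.00212 and 0.0271 for the 10) reassigned sex and so removed the shift that unequal slopes turn into spread, and 1 on Cd74 alone (0.926 above the mean of these genes, p = 0.000940) rested on the top gene of the pattern, which excludes nothing for the others. Trem2, left out of the 10 genes for its low level (mean log2 value 4.28), differed by 0.139, below their range. Border tissue in more females stays open too, since Enpp2 (-0.29, SE 0.386, against a mean shift of 0.53) is the 1 measured choroid plexus gene and is also expressed by oligodendrocytes, and a difference of microglial state between the sexes stays open, untested.

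The third pattern is Acp1 lower and Mapt higher in transgenic mice. In all 28 transgenic against 7 WT_veh mice Acp1 was at 0.687-fold (log2 -0.54, adjusted p = 0.000329) and Mapt at 1.31-fold (0.39, adjusted p = 0.191). Of 100 splits 1, the real one, held any gene with a limma p as small as that of Acp1 (4.33e-07, 5.11e-06 at the smallest in another). This test covers Acp1, and no split test was made for Mapt. An oligodendrocyte share is argued against, since 95.5% (Mapt) and 105% (Acp1) of the differences remained with the myelin score as a covariate. What lowers Acp1 stays open. Mapt was above WT_veh in each of the 4 groups, by 0.32 (SE 0.128) to 0.46. For both genes the 4 groups were set against the same 7 WT_veh mice, so their differences are not independent. A probe reading the human tau transgene may be a source of this difference, but the test could not decide it. Its rule asked only for a rise, was set after these values were seen and named no size. An altered expression of mouse Mapt stays open as well and was not tested.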

How the results depend on the processing

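The settings with the myelin score, the first principal component or the sample median as a covariate, the one without 3 mice, the list permutation and the list tests without each mouse in turn were chosen only after the data were seen, and these tests are named as such here. The causes of the changes below were not tested, except where fewer genes or mice were used.

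Against WT_veh the Acp1 difference kept its direction under every setting in which Acp1 was tested. Calls in AD_veh against WT_veh (1) became 2 with median centring, 0 with quantile normalization, 0 without the dimmest 25% of genes (Acp1 not among the 570 left), 0 with trend and robust moderation and 5 with sample weights. In ADPolB_veh against WT_veh (0) they became 1 with a replicate block, 1 with no sex term, 2 with median centring, 3 with quantile normalization, 441 with sample weights and 1 with the myelin score as a covariate. In AD_UA against WT_veh (1) they became 0 with only the groups compared, 0 without the dimmest genes, 134 with sample weights and 2 with the myelin covariate, and in ADPolB_UA against WT_veh (1) 0 with only the groups compared, 0 without the dimmest genes, 0 with trend and robust moderation and 285 with sample weights. Sample weights also gave 209 calls in ADPolB_veh against AD_veh, 2 in AD_UA against AD_veh, 20 in ADPolB_UA against ADPolB_veh, 18 for averaged Urolithin A, 21 for sex and 171 for the sex difference of the AD_veh effect, where there were 0. For sex, median centring and quantile normalization gave 1 each, and the myelin score, the component and the sample median as covariates 30, 35 and 17.

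Leaving out each mouse in turn gave 0 to 2 calls in AD_veh and 0 to 5 in ADPolB_veh against WT_veh, 1 to 3 in AD_UA and 0 to 2 in ADPolB_UA against WT_veh, 0 to 1 in ADPolB_UA against ADPolB_veh and for averaged Urolithin A, and 0 to 11 for sex. The 5 came without WT_veh 5, the 3 without AD_UA 1, the 11 without AD_veh 2.

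Directions of App turned at values near 0. With sample weights App was 0.0261 in ADPolB_veh against WT_veh, 0.0347 against AD_veh and -0.0132 in AD_UA against AD_veh. App in AD_UA against AD_veh was -0.00143 with no sex term and -0.0025 with only the groups compared. Without the 3 mice App was 0.0166 in ADPolB_veh and -0.0116 in AD_UA against AD_veh. App for sex was -0.0214 with a replicate block, -0.0141 with median centring and -0.0274 with quantile normalization. Without 1 mouse, the lowest and highest were -0.0357 and 0.0143 for App in AD_veh and -0.0543 and 0.0155 in ADPolB_veh against WT_veh, -0.0417 and 0.0300 for App in ADPolB_veh against AD_veh, -0.0317 and 0.0290 for App in AD_UA against AD_veh and -0.0121 and 0.155 for Mapt in ADPolB_UA against ADPolB_veh. The myelin and presynapse lists in AD_UA against AD_veh turned without the 3 mice (adjusted p = 0.714 and 0.828), as did myelin in the sex difference of the Urolithin A effect (0.962).

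List calls were 0 in all 12 comparisons with an estimated correlation and with fry, and 0 in the 9 with a list permutation. Without the 3 mice there were 1 in AD_veh against WT_veh (3 with all mice), 8 in ADPolB_veh against AD_veh (5), 0 in AD_UA against AD_veh (2), 1 for averaged Urolithin A (2) and 4 for its difference between genotypes (1). Median centring gave 7 in ADPolB_veh against WT_veh (4), 3 in ADPolB_veh against AD_veh (5), 0 for the difference between genotypes (1) and 4 in ADPolB_UA against WT_veh (1). A replicate block gave 1 for averaged Urolithin A (2), 3 for the difference between genotypes (1), 1 in AD_UA against WT_veh (2), 2 for sex (4) and 1 for the sex difference of the Urolithin A effect (4). Without each mouse in turn, list calls ranged from 1 to 3 in AD_veh and 4 to 9 in ADPolB_veh against WT_veh, 1 to 8 in ADPolB_veh against AD_veh, 0 to 2 in AD_UA against AD_veh, 1 to 5 in ADPolB_UA against ADPolB_veh, 1 to 3 for averaged Urolithin A, 0 to 3 for its difference between genotypes, 0 to 2 in AD_UA and 0 to 3 in ADPolB_UA against WT_veh, 3 to 6 for sex, 3 to 5 for the sex difference of the AD_veh effect and 1 to 6 for that of the Urolithin A effect. Median centring moved the median of all genes by up to 0.144 on the log2 scale.

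Rescaling on panel reference genes (0 measured members), a pseudocount (values already on the log2 scale), and no sex term or only the groups compared for the sex result were not run. The signal over background that would limit dim genes such as Acp1 is not given in the sources used here.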

Other observations

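Across the 4 transgenic groups, all set against the same WT_veh mice, Acp1, a protein tyrosine phosphatase gene, was at 0.642-fold to 0.712-fold of WT_veh, and Mapt, the tau gene, at 1.25-fold to 1.38-fold. With the myelin score as a covariate Sestd1 also passed in the comparison of all transgenic mice with WT_veh (1.18-fold, log2 0.24, SE 0.05, adjusted p = 0.0206; 1.08-fold without it), a gene chosen after its values were seen.

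The tests reported in this part that were chosen only after the result was seen are the comparison of all transgenic mice and the levels in mice with high Adora2a, and the splits were planned. Of 100 splits of the same mice each, as many genes at an unadjusted p below 0.05 as in the real one came from 26 for AD_veh against WT_veh (50 genes, 363 at most in another split), 46 for ADPolB_veh against AD_veh (33, 230), 18 for AD_UA against AD_veh (71, 288) and 24 for ADPolB_UA against ADPolB_veh (43, 272). For Urolithin A averaged over genotypes they were 11 (90, 293) and for its difference between genotypes 46 (29, 309). Against WT_veh they were 18 for AD_UA (41, 258) and 15 for ADPolB_UA (76, 280). For sex they were 22 (65, 261), for the sex difference of the AD_veh effect 66 (13, 249) and for that of the Urolithin A effect 97 (4, 243). In none of these 11 comparisons can chance be excluded for the count. Splits with several times the real count point to a structure of the samples that the groups do not follow.

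AD_veh 2, AD_UA 3 and AD_UA 8, the mice with high Adora2a, also had high values of Pde1b (11.27, 10.24 and 9.73, at most 9.07 in the other mice), Ptpn5 (11.64, 10.84 and 10.62, at most 10.30) and Rgs4 (12.76, 12.95 and 12.93, at most 12.56), 3 genes chosen after their values were seen. The highest value in the other mice belonged to ADPolB_UA 6 for each of these 3 genes and for Adora2a (6.07). Gabrd, also chosen after its values were seen, was high in the 3 mice with high Adora2a as well (9.98 or more). For Gabrd the highest value in the other mice was that of AD_UA 7 (9.36), above ADPolB_UA 6 (9.34). ADPolB_UA 6 lay under the Adora2a level used and stayed in the settings without the 3 mice. Residuals of mice with the same replicate number in different groups correlated at a mean r of -0.06 over 62 pairs (-0.74 to 0.76).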
